A study of Arabidopsis thaliana with 12 samples.

How the data were processed

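Total RNA of whole seedlings was hybridised to 12 Agilent one-colour arrays with Cy3, 3 for each of WT, WT + SA, 3xbhlh and 3xbhlh + SA, per the labels. The deposited intensity values are processed signals of Agilent Feature Extraction 10.7.3.1, background-subtracted by the authors' software per the file headers. The deposited series table holds the same intensity to 3 significant digits, with gaps of at most 0.497%. Every sample was placed in its group by its label. The replicate number is also the slide and its scan date in the file headers, so replicate and slide are one factor. Each array held 45220 spots, of which 43803 were no controls, for 43603 probes. A locus was assigned to 39057 probes (38413 from the systematic name and 644 from the gene name), and 4546 had none. These were 29043 loci, 28608 of them in the gene table of assembly TAIR10.1, which was used only for names. Neighbouring loci were ordered by their locus numbers. The file headers name another build of the genome annotation, so no coordinates are given. Of the tested loci 13209 have no symbol of their own.

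Signals of spots of the same probe were averaged, log2-transformed and expressed relative to the array's 75th percentile over non-control probes. A spot is well above background, per the file headers, when it passes a significance test and exceeds 13 background standard deviations. Probes were kept if well above background on all 3 arrays of at least 1 group, which left 34225 probes, 31577 with a locus. Where a locus had several (6781 loci), the probe with the highest mean over the 12 arrays was taken, which gave 22719 loci. Array depth is given by the share of spots well above background, 76.1% to 79.7%; no spot was saturated, and 6 to 27 spots an array were outliers. The number of arrays limits the precision. The values of 12.2% to 15.5% of the spots of an array were surrogates, which the software sets where a signal does not exceed background.

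All 12 arrays were fitted together with limma 3.58.1 in R 4.3.3, by lmFit, contrasts.fit and eBayes, and p values were adjusted by the method of Benjamini and Hochberg over the loci of each comparison. The comparisons were SA in WT, SA in 3xbhlh, genotype without SA, genotype with SA, their mean, and the interaction. Tables and plots were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9. The shift of 22 gene lists with 389 loci was tested over 22655 loci measured on all arrays with camera, two-sided, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists; camera asks whether a list shifts more than other genes. An estimated correlation and fry were alternatives. The p value of fry tests whether the genes of a list move, on balance, one way, and its mixed p value whether they change in either direction; neither compares the list with other genes. The lists were targeted genes, root Fe acquisition, Fe deficiency regulation and distribution, Fe storage, Zn and Cu homeostasis, SA signalling, SA synthesis, detoxification, jasmonate, ethylene, auxin, photosynthesis, root hairs, ER protein folding, heat shock, camalexin and indole glucosinolates, aliphatic glucosinolates, phenylpropanoids, touch and wounding, the clock, mitosis and common reference genes. Not tested, because no probe was kept, were VTL3, VIT1, MTP2, FRO4, FRO5, CITF1 and BSMT1.

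Genes were named by a rule: the targeted genes; for each comparison of a pair of groups, the 12 highest and 12 lowest loci that passed and whose arrays did not overlap; for the interaction and the averaged difference, the 10 smallest p values among those that passed, or up to 5 that did not; in each list up to 4 members with the smallest p; and 17 genes of SA and Fe biology whatever their values. Named loci without a symbol were in part left out, and in long comparisons a selection of the named genes is given. Comparisons, their tests, lists, the naming rule and all alternatives but 1 were chosen before the data were examined. Tests of explanations for WT replicate 3 and for the array labelled 3xbhlh + SA replicate 3 were chosen after the results were seen. So was the test of linked DNA around the targeted genes. The alternative without both WT replicate 3 and the array labelled 3xbhlh + SA replicate 3 was chosen after seeing the data. The other alternatives were normexp background correction with an offset of 50, median centring, quantile normalization, the replicate as a block or the slide as a random block, no filter, a filter on all 12 arrays, the mean of probes, only the 6 arrays compared, the deposited series table, array weights, a trended and robust spread, adjusted p under 0.01, a 2-fold minimum, and each array and each replicate number left out.

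Whether equal replicate numbers pair the samples was checked by the correlation, across loci, of the deviations of both groups' arrays from their group means. For replicates 1, 2 and 3 it was 0.205, 0.269 and 0.0944 for SA in WT, 0.333, 0.246 and 0.384 for SA in 3xbhlh, 0.170, 0.247 and 0.115 for genotype without SA, and 0.450, 0.353 and 0.534 for genotype with SA. All but the first set exceeded 0.1 throughout, and blocked counts stand beside the genotype counts, which they moved. The fit was tested on simulated data of 22655 loci with 100 loci changed at each of 2 sizes: 68% (SA in WT), 75% (SA in 3xbhlh), 69% (genotype without SA), 74% (genotype with SA), 57% (interaction) and 89% (averaged) were recovered at a log2 change of 1, and 90%, 97%, 94%, 97%, 86% and 99% at 2. There 6 to 14 unchanged loci passed, and the 1 shifted list passed while none of 21 others did. The simulated noise was independent between arrays and between loci, with no slide effect and no array apart. These rates therefore hold for that simple case and check the code, not the conditions of the real arrays. Probes without a locus took no part in the comparisons.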

Results

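Transcript levels were measured on 12 one-colour Agilent arrays, each hybridised with Cy3-labelled total RNA from entire Arabidopsis thaliana seedlings that were 6 days old and had been raised in medium lacking Fe. Wild type (WT) and 3xbhlh, a mutant with lesions in BHLH39, BHLH100 and BHLH101, had received 100 µM salicylic acid (SA), a plant hormone of the immune response, or a mock treatment for 6 h. Each of the 4 groups had 3 replicates, which the series design calls biological. The 3 mutated genes encode basic helix-loop-helix transcription factors of subgroup Ib, whose transcripts are known to accumulate under Fe deficiency. Between 76.1% and 79.7% of the spots of an array were well above background, and the 75th percentile of the processed signal ran from 977 on WT replicate 3 to 2044 on the array labelled 3xbhlh + SA replicate 3. The first principal component of the 12 arrays held 73.9% of the variance and separated the SA-treated arrays from the mock arrays. The second held 8.78% and set WT replicate 3, with a score of 74.1, apart from the other 11 arrays, which had scores from -23.3 to 10.2. Differences are on the log2 scale ± the standard error of the fit, with n = 3 arrays in each group, and a locus passed at a limma adjusted p under 0.05 over the 22719 loci tested.

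The targeted transcripts were lower on each of the 6 arrays labelled 3xbhlh than on any WT array. Without SA, BHLH39 (AT3G56980) stood at 0.67 ± 1.04 (SD, n = 3) in WT and -5.20 ± 0.62 in 3xbhlh, relative to the 75th percentile of the array. BHLH101 (AT5G04150) stood at 1.14 ± 1.55 in WT and was not well above background on any 3xbhlh array, and BHLH100 (AT2G41240), at 1.75 ± 1.84 in WT, was well above background on 1 of the 3 3xbhlh arrays. With SA, BHLH39 stood at 1.83 ± 0.41 in WT and -3.28 ± 2.498 in 3xbhlh. The array labelled 3xbhlh + SA replicate 3 held much more of all 3 transcripts than the other 5 arrays of the mutant. On it BHLH39 lay at -0.69, BHLH100 at -0.40 and BHLH101 at -0.66, whereas replicates 1 and 2 of that group had -3.48 and -5.68, -4.06 and -9.05, and -4.41 and -6.81. Among the other mutant arrays levels varied too. BHLH100 lay at -5.82 on 3xbhlh replicate 3 but at -10.33 and -10.40, not well above background, on 3xbhlh replicates 1 and 2. With SA, replicate 1 held more of all 3 transcripts than replicate 2. Every direction given for 3xbhlh with SA rests in part on the array labelled 3xbhlh + SA replicate 3. Averaged over both treatments, 3xbhlh differed from WT by -5.49 ± 0.71 for BHLH39 and by fitted values of -8.76 ± 1.38 for BHLH100 and -7.70 ± 0.94 for BHLH101, with adjusted p = 0.0070, 0.018 and 0.0052. Where the probes lie relative to the mutations is not given in the sources used here, so these levels check the labels only that far.

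**Figure D1:**
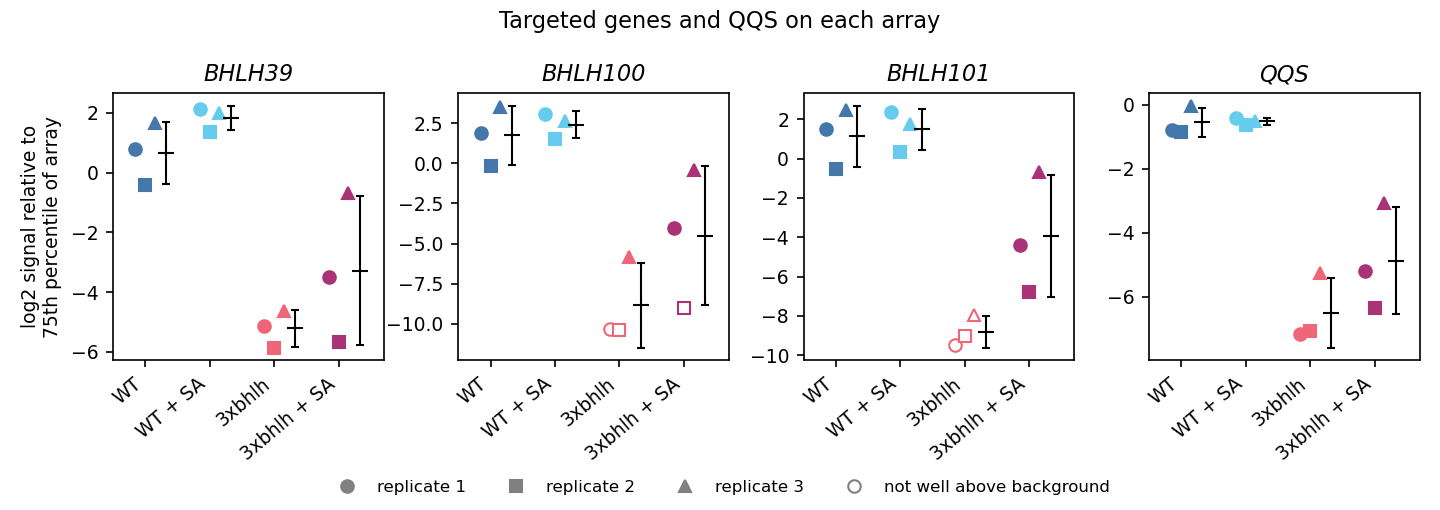
Processed signal of BHLH39, BHLH100, BHLH101 and QQS on each of the 12 arrays (vertical axis, log2 relative to the array's 75th percentile; circle, square and triangle for replicates 1, 2 and 3; open symbols not well above background; bars mean ± SD of 3 arrays). On the array labelled 3xbhlh + SA replicate 3 the targeted transcripts lay at -0.69, -0.40 and -0.66, and QQS at -3.07.

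Comparison of WT with and without SA addressed the response of Fe-deficient WT seedlings to the hormone. Of 25 measured SA signalling and SA marker genes, 22 rose, 0 fell, and the list median was 3.41 (camera adjusted p = 3.1e-18, and adjusted p = 0.0020 with an estimated correlation). PCC1, a gene regulated by pathogens and the circadian clock, rose by 10.37 ± 0.39, and NIMIN1, which encodes a partner of the SA receptor NPR1, by 9.41 ± 0.27. WRKY70 rose by 5.46 ± 0.24, WRKY54 by 5.44 ± 0.15 and the glutaredoxin gene GRX480 by 4.08 ± 0.38. PR1, the classical pathogenesis-related marker, was not well above background on any mock array and was at least 90.8-fold higher with SA (adjusted p = 1.1e-06), a bound in which each dim signal was raised to at least the lowest signal well above background on its array. PR5, a thaumatin-like protein gene, rose by 1.67 ± 0.31, whereas PR2, a glucanase gene, did not pass (1.504 ± 0.73, adjusted p = 0.11), though it did with the replicate block (adjusted p = 0.0061). Among 13 genes of SA synthesis and metabolism 8 rose and 1 fell, with a median of 1.56 (camera adjusted p = 8.4e-06, and adjusted p = 0.082 with an estimated correlation). The SA hydroxylase genes S3H (6.23 ± 0.29) and S5H (3.499 ± 0.14) and the regulator SARD1 (4.93 ± 0.15) were among those that rose, and ICS1, the isochorismate synthase of SA synthesis, did not pass (0.01 ± 0.17, adjusted p = 0.98).

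Genes outside these lists rose as far. LURP1, known from the response to downy mildew, rose by 9.25 ± 0.17, and ARD3, an acireductone dioxygenase gene, by 8.85 ± 0.83. WRKY59, measured on 1 of the 3 mock arrays, rose by 9.85 ± 0.50. ANK and PCR1, not well above background on the mock arrays, were at least 660.0-fold and at least 231-fold higher.

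Transcripts of chemical detoxification and of several stress responses rose with SA as well. Of 41 detoxification genes 37 rose and 2 fell, with a median of 2.41 (camera adjusted p = 6.7e-24, and adjusted p = 0.030 with an estimated correlation). The transporter gene ABCG40 rose by 7.22 ± 0.22, the glutathione transferase gene GSTU11 by 4.67 ± 0.13 and the glucosyltransferase gene UGT74E2 by 4.26 ± 0.15. All 13 heat shock genes rose, with a median of 2.95, or 2.89 with its dim members at their bound (camera adjusted p = 1.1e-07, and adjusted p = 0.26 with an estimated correlation), among them the small heat shock protein gene HSP23.6 (4.85 ± 0.41) and HSP101 (2.73 ± 0.33). Of 12 genes of touch, wounding and handling stress 11 rose, with a median of 2.41 (camera adjusted p = 1.1e-07, and adjusted p = 0.24 with an estimated correlation). The calmodulin-like gene CML37 rose by 5.70 ± 0.20 and the zinc finger gene ZAT12 by 4.37 ± 0.12. Of 18 genes of endoplasmic reticulum (ER) protein folding 9 rose and none fell, with a median of 0.43 (camera adjusted p = 5.9e-05, and adjusted p = 0.49 with an estimated correlation), including BZIP60, a regulator of the unfolded protein response (1.64 ± 0.10), and ERDJ3A (2.25 ± 0.19). Of 16 ethylene genes 8 rose and 1 fell, with a median of 0.63 (camera adjusted p = 0.0030, and adjusted p = 0.35 with an estimated correlation). ERF6 (2.07 ± 0.15) and the ACC synthase gene ACS6 (2.03 ± 0.14) rose.

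Among the genes that fell were FLA6, a fasciclin-like arabinogalactan protein gene measured on 2 of the 3 SA arrays (-5.23 ± 0.48), and PRP1, a proline-rich wall protein gene (-4.22 ± 0.47). Of 16 root tissue and root hair markers 12 fell and 1 rose, with a median of -1.03 (camera adjusted p = 0.0019, and adjusted p = 0.24 with an estimated correlation), including the root hair regulator RSL4 (-3.37 ± 0.20) and the expansin gene EXPA18 (-2.65 ± 0.35). All 9 genes of aliphatic glucosinolates, sulphur-rich defence compounds, fell, with a median of -1.82 (camera adjusted p = 0.0012, and adjusted p = 0.49 with an estimated correlation), among them CYP79F2 (-2.25 ± 0.35), SOT18 (-1.93 ± 0.24) and their regulator MYB28 (-1.01 ± 0.13). Camalexin and indole glucosinolate genes went both ways (5 higher and 3 lower of 14; camera adjusted p = 0.39). PAD3, the last enzyme of camalexin synthesis, rose by 3.18 ± 0.20 and MYB51 by 1.63 ± 0.18, and MYB34 (-1.29 ± 0.12) and CYP79B3 (-1.44 ± 0.18) fell.

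Fe genes moved in both directions with SA, as did the tested loci as a whole. Of all 22719 loci 49.2% passed with SA in WT, 4564 higher and 6610 lower. The counts of these lists are to be read beside that share. Of 24 genes of root Fe acquisition 4 rose and 8 fell (median -0.13, camera adjusted p = 0.90). FIT, the master regulator of Fe uptake, rose by 0.41 ± 0.10 and ZIP8 by 1.43 ± 0.17, the proton pump gene AHA2 (-0.57 ± 0.11) and the nicotianamine synthase gene NAS1 (-0.57 ± 0.07) fell, and the Fe transporter gene IRT1 (0.75 ± 0.33, adjusted p = 0.082) and the ferric reductase gene FRO2 (-0.10 ± 0.16, adjusted p = 0.62) did not pass. Of 24 genes of Fe deficiency regulation and distribution 4 rose and 1 fell (median 0.20, camera adjusted p = 0.16), with BHLH11 rising by 1.59 ± 0.14. Of 12 Fe storage and Fe-sufficiency genes 2 fell, the ferritin genes FER3 (-1.43 ± 0.21) and FER4 (-1.14 ± 0.29), and the list as a whole did not pass (median -0.59, camera adjusted p = 0.39). WT replicate 3 stood apart on these lists: its medians differed from those of the other WT arrays by 0.98 for Fe regulation and -1.18 for Fe storage. Without that array both lists passed, at medians of 0.59 (adjusted p = 0.0025; 0.0024 to 0.90 over 29 alternatives) and -1.06 (adjusted p = 0.023; 0.0098 to 0.94 over 29 alternatives). IRT1 then stood at 0.31 (adjusted p = 0.25). FER1 then changed by -2.39 (adjusted p = 0.0069) in place of -1.25 ± 0.86 (adjusted p = 0.25; 0.0013 to 0.66 over 28 alternatives), and BHLH38, the fourth gene of subgroup Ib, by 1.58 (adjusted p = 0.0072) in place of 0.89 ± 0.54 (adjusted p = 0.20; 0.0072 to 0.68 over 28 alternatives). None of the targeted genes passed with SA in WT (BHLH39 1.16 ± 1.01, adjusted p = 0.36; BHLH100 0.65; BHLH101 0.34). Without both WT replicate 3 and the array labelled 3xbhlh + SA replicate 3 they stood at 1.65, 1.53 and 1.01 (adjusted p = 0.063, 0.48 and 0.38).

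The remaining lists did not pass in WT. Jasmonate genes (25 measured, 2 higher and 4 lower, median -0.43, camera adjusted p = 0.73) had medians of 0.23, 0.26 and -1.45 on slides 1, 2 and 3, and on WT replicate 3 they lay 1.63 above the other WT arrays. Auxin genes (7 higher and 7 lower of 22, camera adjusted p = 0.82) included GH3.3, which conjugates auxin to amino acids (4.18 ± 0.21), and the auxin carrier gene PIN3 (-0.77 ± 0.11). Zn and Cu homeostasis genes (2 higher and 4 lower of 19, camera adjusted p = 0.90) included ZIP3 (-1.56 ± 0.22) and PCR2 (1.46 ± 0.16). Clock genes (4 higher and 3 lower of 11, camera adjusted p = 0.90) included LHY (1.48 ± 0.34) and ELF4 (-1.41 ± 0.24). Mitotic genes (4 lower of 9, median -0.41) had a camera adjusted p of 0.096. Photosynthesis and chlorophyll genes (4 lower of 29, adjusted p = 0.30), phenylpropanoid genes (4 lower of 17, adjusted p = 0.56) and common reference genes (1 higher and 2 lower of 8, adjusted p = 0.85) did not pass either. In fits lacking 1 array, a call appeared for mitotic genes without WT replicate 3 or WT + SA replicate 1 (adjusted p 0.015 to 0.031). Photosynthesis genes gained it without WT + SA replicate 3 (adjusted p = 0.026). Median and mean differed in sign for auxin (-0.20 and 0.08) and clock genes (-0.19 and 0.17), where camera pointed up. Adjusted over the list alone, the counts of genes higher and lower were the same except for Fe regulation (3 and 0), jasmonate (0 and 0), ethylene (9 and 1), photosynthesis (0 and 0), root hairs (1 and 13), camalexin (6 and 3), phenylpropanoids (0 and 2) and the clock (4 and 5).

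In all, 11174 of 22719 loci passed in WT, 4564 higher and 6610 lower with SA, and 3574 of them changed at least 2-fold, 1931 up and 1643 down. On each of the 3 slides taken alone, 10992 of the 11174 kept their direction. The median over all tested loci was -0.13, and 40.8% of the loci that passed were higher, against 47.5% with the arrays centred on their medians. Of 22 lists 9 passed with the preset correlation and 2, SA signalling and detoxification, with an estimated one. With the 4 arrays of replicate 1 left out 6197 loci passed, and with those of replicate 2 left out 6803. Without both WT replicate 3 and the array labelled 3xbhlh + SA replicate 3 11568 passed.

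**Figure D2:**
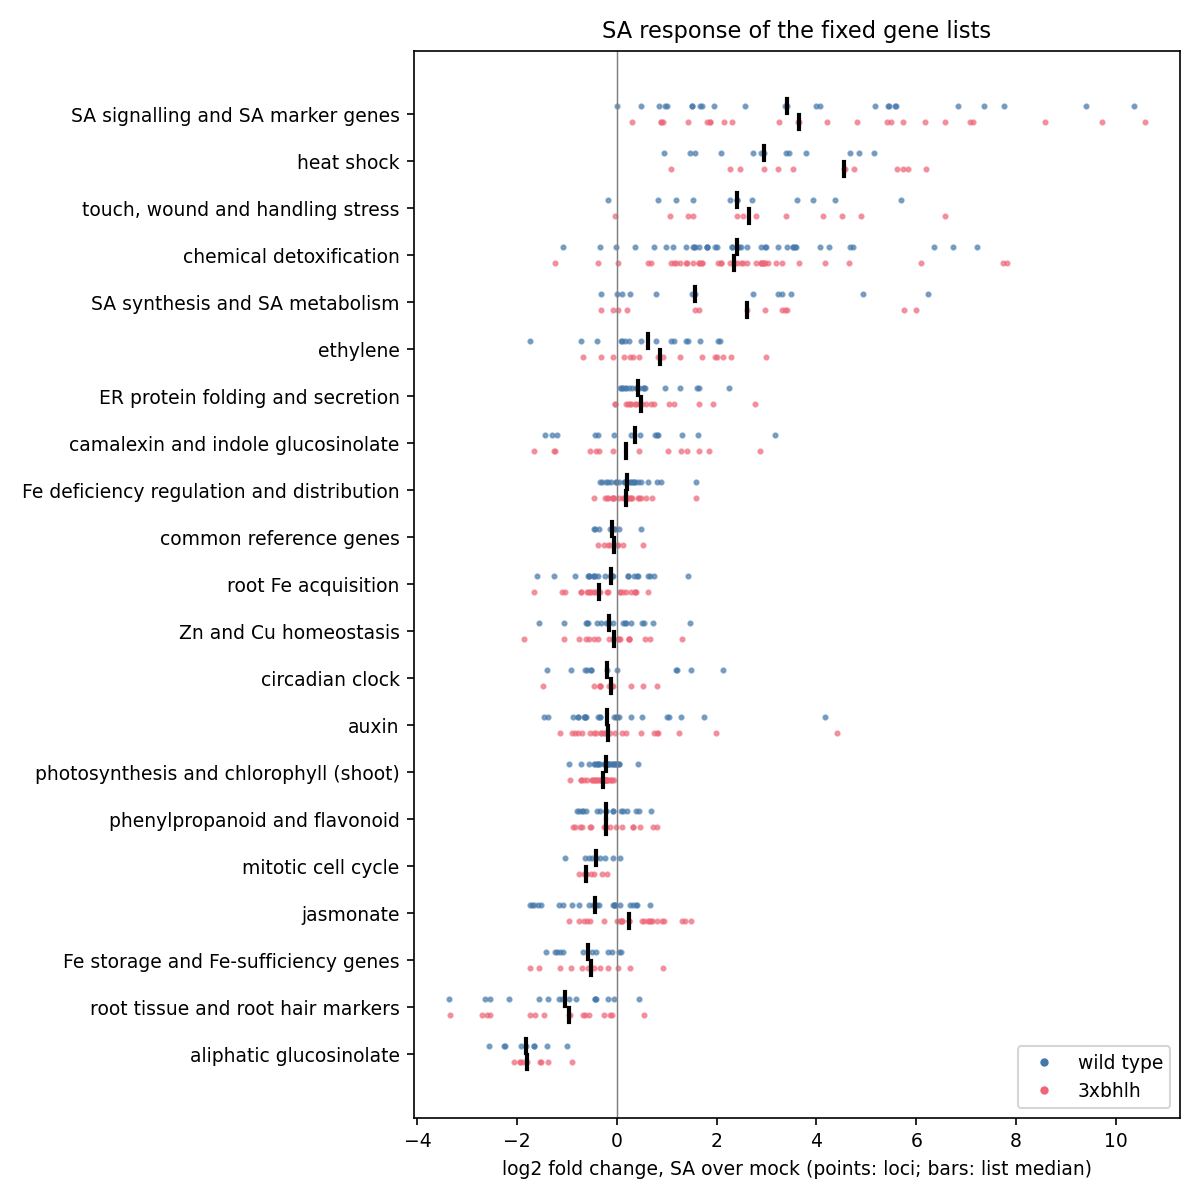
Log2 fold change with SA over mock (horizontal axis) of each measured locus of 21 fixed gene lists, in WT (upper, blue) and 3xbhlh (lower, red), with a black bar at each list median. The median of SA signalling genes was 3.41 in WT and 3.66 in 3xbhlh, and that of aliphatic glucosinolate genes -1.82 and -1.81.

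In 3xbhlh the same hormone treatment raised the SA and stress genes and lowered root hair and aliphatic glucosinolate genes. Of 25 SA signalling genes 23 rose and none fell, with a median of 3.66 (camera adjusted p = 2.8e-20, and adjusted p = 0.0014 with an estimated correlation). PCC1 rose by 10.59 ± 0.39, NIMIN1 by 9.72 ± 0.27, WRKY70 by 6.57 ± 0.24 and GRX480 by 4.82 ± 0.38. PR1 was at least 84.0-fold higher, PR2 rose by 2.31 ± 0.73 (measured on 1 of the 3 mock arrays; adjusted p = 0.024) and PR5 by 2.14 ± 0.31. In fits lacking 1 array, the call was lost for PR2 without 3xbhlh replicates 2 or 3 or 3xbhlh + SA replicate 1 (adjusted p up to 0.091). Genes of SA synthesis and metabolism rose at 9 of 13 and fell at 1, with a median of 2.61 (camera adjusted p = 3.1e-06, and adjusted p = 0.067 with an estimated correlation), SARD1 by 5.76 ± 0.15 and S3H by 5.99 ± 0.29. ICS1 did not pass (-0.09 ± 0.17, adjusted p = 0.69). LURP1 rose by 9.28 ± 0.17, WRKY62 by 8.58 ± 0.64 (measured on 2 of the 3 mock arrays) and ARD3 by 8.53 ± 0.83, while ANK, WRKY66 and the egg cell gene EC1.2, not well above background on the mock arrays, were at least 1126-fold, at least 74.5-fold and at least 56.4-fold higher.

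Detoxification genes rose at 38 of 41 and fell at 2, with a median of 2.36 (camera adjusted p = 1.5e-23, and adjusted p = 0.032 with an estimated correlation), ABCG40 by 7.82 ± 0.22 and the alternative oxidase gene AOX1D, measured on 2 of the 3 mock arrays, by 7.74 ± 0.30. All 13 heat shock genes rose (median 4.56, or 4.05 with its dim members at their bound; camera adjusted p = 1.4e-09, and adjusted p = 0.18 with an estimated correlation), with HSP23.6 at 5.83 ± 0.41 and HSP101 at 3.53 ± 0.33. Touch and wounding genes rose at 11 of 12 (median 2.65; camera adjusted p = 1.0e-08, and adjusted p = 0.18 with an estimated correlation), CML37 by 6.59 ± 0.20 and WRKY33 by 3.39 ± 0.21. Ethylene genes rose at 10 of 16 (median 0.87; camera adjusted p = 1.9e-04, and adjusted p = 0.18 with an estimated correlation), ERF6 by 2.99 ± 0.15, and ER folding genes at 10 of 18 (median 0.48; camera adjusted p = 1.5e-05, and adjusted p = 0.45 with an estimated correlation), ERDJ3A by 2.76 ± 0.19. Root hair markers fell at 12 of 16 and rose at 1 (median -0.96; camera adjusted p = 0.0013, and adjusted p = 0.18 with an estimated correlation), with RSL4 at -3.34 ± 0.20 and PRP3 at -2.60 ± 0.38. Aliphatic glucosinolate genes fell at 8 of 9 (median -1.81; camera adjusted p = 0.0019, and adjusted p = 0.55 with an estimated correlation), with CYP83A1 at -1.87 ± 0.30. Mitotic genes fell at 6 of 9 (median -0.62; camera adjusted p = 0.015, and adjusted p = 0.59 with an estimated correlation), with CYCB2;1 at -0.75 ± 0.16.

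Of all tested loci 47.7% passed with SA in 3xbhlh, 4330 higher and 6506 lower. Root Fe acquisition genes rose at 2 and fell at 11 of 24 (median -0.37, camera adjusted p = 0.43), with NAS1 at -1.03 ± 0.07, NAS2 at -0.54 ± 0.12 and AHA2 at -0.45 ± 0.11, FIT at 0.37 ± 0.10, and no call for IRT1 (0.06 ± 0.33, adjusted p = 0.90) or FRO2 (-0.34 ± 0.16, adjusted p = 0.10). FER3 fell (-1.56 ± 0.21), as did FER4 (-0.93 ± 0.29). In fits lacking 1 array, the call was lost for FIT without 3xbhlh replicate 1 or 3xbhlh + SA replicate 2 (adjusted p up to 0.065). FER4 lost it without 3xbhlh replicates 1 or 2 or the array labelled 3xbhlh + SA replicate 3 (adjusted p up to 0.095). FER1 did not pass (-1.75 ± 0.86, adjusted p = 0.12), and the Fe storage (camera adjusted p = 0.45) and Fe regulation lists (adjusted p = 0.18) did not either. BHLH101, one of the targeted genes, was at least 15.7-fold higher with SA on the 3xbhlh arrays (adjusted p = 0.012). The array labelled 3xbhlh + SA replicate 3 held the most of it. Without that array BHLH101 was at least 5.02-fold higher (adjusted p = 0.029, and 0.0016 to 0.14 over 27 alternatives). Leaving out that array does not settle a rise with SA, since the targeted transcripts also varied among the remaining mutant arrays. BHLH101 lay at -4.41 and -6.81 on 3xbhlh + SA replicates 1 and 2. BHLH39 (1.92 ± 1.01, adjusted p = 0.14) and BHLH100 (4.35 ± 1.96, adjusted p = 0.091; measured on 1 of the 3 mock arrays) did not pass. With the replicate block BHLH39, BHLH100 and FER1 passed (adjusted p = 0.043, 0.017 and 0.035), whereas without the array labelled 3xbhlh + SA replicate 3 they stood at 0.63, 2.30 and -1.19 (adjusted p = 0.52, 0.33 and 0.34). FER1 passed without WT replicate 3 (-1.75, adjusted p = 0.016) and without both arrays (-1.19, adjusted p = 0.046; 0.0086 to 0.34 over 28 alternatives). Jasmonate genes had a median of 0.25 (camera adjusted p = 0.13), photosynthesis genes one of -0.29 (adjusted p = 0.053) and the targeted genes one of 4.35, or 3.98 with BHLH101 at its bound (adjusted p = 0.17). In fits lacking 1 array, a call appeared for photosynthesis genes without WT replicate 3, 3xbhlh replicate 2, WT + SA replicates 1 or 3 or the array labelled 3xbhlh + SA replicate 3 (adjusted p 0.016 to 0.049). Targeted genes gained it without 3xbhlh + SA replicate 2 (adjusted p = 0.027). Jasmonate genes gained it without WT replicate 3 (adjusted p = 0.049). The other lists did not pass: Zn and Cu (adjusted p = 0.85), auxin (adjusted p = 0.45), camalexin (adjusted p = 0.46), phenylpropanoids (adjusted p = 0.46), the clock (adjusted p = 0.71) and reference genes (adjusted p = 0.86). Median and mean differed in sign for auxin (-0.18 and 0.20), and camera pointed up for reference genes, whose median was -0.06. Adjusted over the list alone, the counts of genes higher and lower differed for SA signalling (24 and 0), ethylene (10 and 1), aliphatic glucosinolate (0 and 9), Fe regulation (2 and 0), Fe storage (0 and 1), jasmonate (2 and 0), photosynthesis (0 and 3), camalexin (6 and 6), clock (0 and 1) and mitotic (0 and 7).

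In all, 10836 loci passed in 3xbhlh, 4330 higher and 6506 lower, with 3616 changed at least 2-fold, and 10818 kept their direction on all 3 slides. With the arrays centred on their medians 4833 were higher and 5283 lower. Of the loci that passed in both genotypes, 3832 rose in both, where independent lists would share 869.85, and 5341 fell in both, where independent lists would share 1893. None passed in opposite directions; 2001 passed in WT only and 1663 in 3xbhlh only, which is no test of a difference. Across the tested loci, which are not independent replicates, the 2 sets of fold changes had a Pearson r of 0.946 and a Spearman rho of 0.897, and the major axis had a slope of 1.02. Without both WT replicate 3 and the array labelled 3xbhlh + SA replicate 3 11193 loci passed. With the 4 arrays of replicate 1 or of replicate 2 left out, 6312 and 6329 passed.

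**Figure D3:**
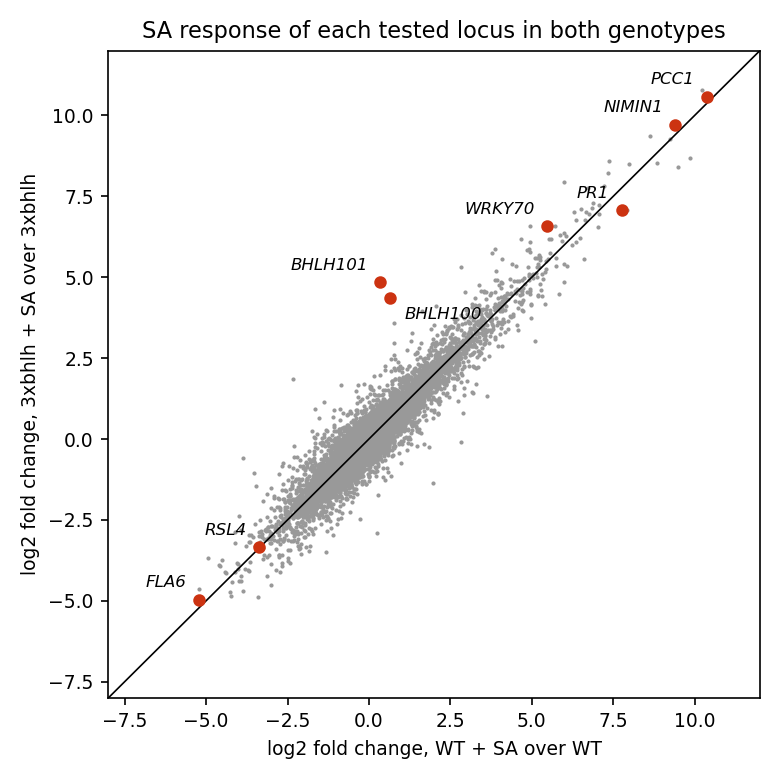
Log2 fold change with SA over mock in WT (horizontal axis) and 3xbhlh (vertical axis), 1 point per tested locus, with the line of equal change and 8 loci named. The mock levels of PR1, and those of BHLH101 in 3xbhlh, were not well above background. BHLH100 was not well above background on 3xbhlh replicates 1 and 2 and on 3xbhlh + SA replicate 2. The positions of these loci on the axes concerned are therefore fitted values and not measured folds. The major axis of all points had a slope of 1.02.

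Comparison of the genotypes without SA addressed how 3xbhlh differed from WT in Fe-deficient seedlings. That comparison cannot separate the 3 mutations from linked DNA around them. Beside the targeted genes, CYP82C4, a hydroxylase of Fe-mobilising coumarins, was lower in 3xbhlh (-2.25 ± 0.27, adjusted p = 0.014), as was QQS, an orphan gene linked to starch content (-5.95 ± 0.73, adjusted p = 0.015). GH3.4, an auxin-conjugating enzyme gene, was at least 3.87-fold lower and GRP17, a pollen oleosin gene, at least 3.56-fold lower. The clock genes CCA1 (2.37 ± 0.33, adjusted p = 0.020) and LHY (2.25 ± 0.34, adjusted p = 0.029) were higher in 3xbhlh, as were ERF71, an ethylene response factor of hypoxia (2.17 ± 0.27), COL1 (1.93 ± 0.30), and the fatty acyl reductase gene FAR6 (2.92 ± 0.51, measured on 1 of 3 WT arrays). M10 (AT2G41280), not well above background in WT, was at least 3.58-fold higher, and AT2G41250 and AT5G54550 were higher by 2.12 ± 0.23 and 2.24 ± 0.20. BHLH39 (-5.87 ± 1.01, adjusted p = 0.047) and BHLH101 (at least 540.1-fold lower, adjusted p = 0.018) passed, and BHLH100, measured on 1 of the 3 3xbhlh arrays, did not (fitted -10.61 ± 1.96, adjusted p = 0.059). With the replicate block BHLH100 passed (adjusted p = 0.017) and FAR6 did not (adjusted p = 0.056). As a list the targeted genes had a median of -9.95, or -9.08 with BHLH101 at its bound (camera adjusted p = 5.1e-06, and adjusted p = 0.27 with an estimated correlation).

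The other Fe genes did not pass singly. Of 24 root Fe acquisition genes 1 was lower, and 5 when adjusted over the list alone; FIT (0.14 ± 0.10, adjusted p = 0.61), IRT1 (0.15 ± 0.33, adjusted p = 0.89), FRO2 (-0.23 ± 0.16, adjusted p = 0.60), BHLH38 (1.01 ± 0.54, adjusted p = 0.48) and FER1 (1.32 ± 0.86, adjusted p = 0.57) did not pass. Without WT replicate 3 IRT1 lay at -0.30, BHLH38 at 1.71 and FER1 at 0.18 (adjusted p = 0.66, 0.12 and 0.94). The list median was -0.14 (camera adjusted p = 0.018, and adjusted p = 0.58 with an estimated correlation), and its adjusted p ran from 1.3e-04 to 0.58 over 29 alternatives. Fe regulation genes had a median of 0.20 (camera adjusted p = 0.014, and adjusted p = 0.62 with an estimated correlation). Of 11 clock genes 2 were higher and none lower (4 and 4 when adjusted over the list alone). Their median (-0.32) and mean (0.37) differed in sign, camera pointed up without passing (adjusted p = 0.89), and fry's mixed test, of change in either direction, passed (adjusted p = 0.0090). No single SA signalling or detoxification gene passed, although their medians of -0.27 (camera adjusted p = 0.0025, and adjusted p = 0.27 with an estimated correlation) and 0.24 (camera adjusted p = 2.4e-05, and adjusted p = 0.58 with an estimated correlation) did with the preset correlation. PR5 (adjusted p = 0.019) and DTX3 (adjusted p = 0.046) passed with the replicate block. Lists whose camera adjusted p passed with no member passing were also jasmonate (-0.40, adjusted p = 0.0014), ER folding (-0.20, adjusted p = 0.0018), phenylpropanoid (0.22, adjusted p = 0.011), root hair (0.20, adjusted p = 0.040) and reference genes (-0.14, adjusted p = 0.040). With an estimated correlation none of these 5 passed (adjusted p = 0.62 for jasmonate and ER folding and 0.58 for the others). Jasmonate medians on slides 1, 2 and 3 were -0.03, -0.01 and -1.39. With 1 array left out, the call was lost for root Fe acquisition genes without WT replicates 1 or 3 or 3xbhlh replicates 1 or 2 (adjusted p 0.051 to 0.12). Fe regulation genes lost it without WT replicates 1 or 2 or 3xbhlh replicate 3 (adjusted p 0.061 to 0.77, with medians from -0.08 to 0.21 against 0.20). Root hair genes lost it without WT replicates 1 or 3 or 3xbhlh replicates 1, 2 or 3 (adjusted p 0.051 to 0.32). Phenylpropanoid genes lost it without WT replicates 1 or 2 or 3xbhlh replicate 1 (adjusted p 0.057 to 0.16). Reference genes lost it without WT replicates 1 or 3 or 3xbhlh replicates 2 or 3 (adjusted p 0.056 to 0.14). SA signalling genes lost it without WT replicate 2 (adjusted p = 0.053). Jasmonate genes lost it without WT replicate 3 (adjusted p = 0.88, with a median of 0.04 in place of -0.40). A call appeared for aliphatic glucosinolate genes without WT replicate 2 (adjusted p = 0.047). Ethylene genes gained it without 3xbhlh replicate 2 (adjusted p = 0.021). Touch genes gained it without 3xbhlh replicate 2 (adjusted p = 0.026). Heat shock genes gained it without WT replicate 3 or WT + SA replicate 3 (adjusted p 0.0090 to 0.036). Mitotic genes gained it without WT replicate 3 (adjusted p = 0.026). Median and mean also differed in sign for Zn and Cu (0.01 and -0.05) and camalexin genes (0.02 and -0.05). Counts adjusted over the list alone, higher and lower, differed for SA signalling (0 and 3), SA synthesis (0 and 2), detoxification (6 and 0), root Fe acquisition (0 and 5), jasmonate (0 and 1), photosynthesis (1 and 2), camalexin (1 and 1), clock (4 and 4) and targeted (0 and 3).

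In all, 75 loci passed, 39 higher and 36 lower in 3xbhlh, each in the same direction on all 3 slides, and 55 of them differed at least 2-fold. With the replicate number, which is also the slide, as a block 164 loci passed, and with the slide as a random block 181. The count fell to 22 without WT replicate 1, 16, 8 and 32 without 3xbhlh replicates 1, 2 and 3, and 43 without WT + SA replicate 2, and stood at 58 without both WT replicate 3 and the array labelled 3xbhlh + SA replicate 3. Of 24 named loci that passed, 6 did so whichever single array was left out (M10, GH3.4, AT2G28820, AT2G41250, AT3G21460 and AT5G54550). The call was lost for CYP82C4, ERF71 and QQS without 3xbhlh replicates 1 or 2 (adjusted p up to 0.062). BHLH101 lost it without WT replicate 1 or 3xbhlh replicates 1 or 2 (adjusted p up to 0.074). GRP17 and CCA1 lost it without WT replicate 1 or 3xbhlh replicates 1, 2 or 3 (adjusted p up to 0.091). LHY lost it in 8 of the 12 cases (adjusted p up to 0.10). COL1 lost it in 8 of the 12 cases (adjusted p up to 0.10). BHLH39 lost it in 10 of the 12 cases (adjusted p up to 0.18). FAR6 lost it in 10 of the 12 cases (adjusted p up to 0.20).

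**Figure D4:**
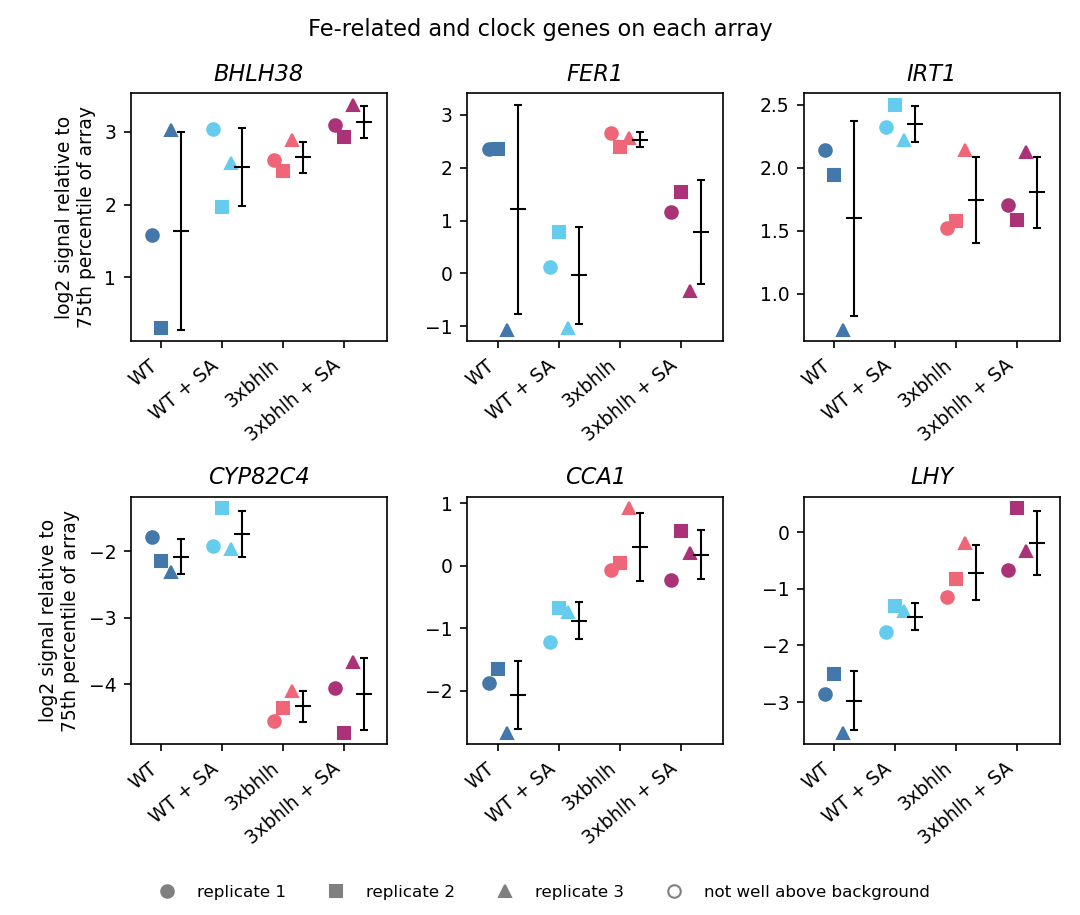
Processed signal of BHLH38, FER1, IRT1, CYP82C4, CCA1 and LHY on each of the 12 arrays (vertical axis, log2 relative to the array's 75th percentile; circle, square and triangle for replicates 1, 2 and 3; bars mean ± SD of 3 arrays). CYP82C4 ran from -4.73 to -3.66 on the 3xbhlh arrays and from -2.31 to -1.35 on the WT arrays, while FER1 lay at -1.07 on WT replicate 3 against 2.35 and 2.36 on the other mock WT arrays.

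With SA, Fe-related genes were again among the loci that differed between the genotypes. CYP82C4 was lower in 3xbhlh (-2.40 ± 0.27, adjusted p = 0.017), and so was ZIP8, a metal transporter gene (-1.34 ± 0.17, adjusted p = 0.022). GRP17, measured on 2 of the 3 3xbhlh + SA arrays (-2.57 ± 0.33), and AT3G07720 (-1.23 ± 0.15) were lower. M10 was at least 4.103-fold higher and FAR6 at least 13.033-fold higher, IDA, a peptide gene of organ shedding, was higher by 2.34 ± 0.28, and the glucanase gene GH9C1 and the subtilase gene ATSBT5.2 were higher by 1.27 ± 0.17 and 0.92 ± 0.13. The targeted genes did not pass here (BHLH39 -5.11 ± 1.01, adjusted p = 0.14; BHLH100 -6.90 ± 1.96, adjusted p = 0.31; BHLH101 -5.44 ± 1.33, adjusted p = 0.23). Without the array labelled 3xbhlh + SA replicate 3 BHLH39 passed at -6.41 (adjusted p = 0.017; 0.014 to 0.97 over 28 alternatives), and BHLH101 had an adjusted p of 0.053 (0.031 to 0.9998 over 27 alternatives). BHLH39 also passed with the replicate block (adjusted p = 0.042). As a list they had a median of -5.44 (camera adjusted p = 3.8e-05, and adjusted p = 0.25 with an estimated correlation). CCA1 (1.06 ± 0.33, adjusted p = 0.36) and LHY (1.30 ± 0.34, adjusted p = 0.26) did not pass.

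Root Fe acquisition genes had a median of -0.32 (camera adjusted p = 3.1e-07, and adjusted p = 0.25 with an estimated correlation). 2 of 24 were lower, and 9 when adjusted over the list alone. SA signalling genes did not pass as a list (median 0.01, mean -0.05, camera pointing up at adjusted p = 0.82), and neither did PR1 (-0.52, adjusted p = 0.89) or NIMIN1 (0.14, adjusted p = 0.97). By camera with the preset correlation, heat shock (0.65, adjusted p = 5.0e-04), auxin (0.23, adjusted p = 2.6e-04), phenylpropanoid (0.17, adjusted p = 0.0040), Fe regulation (0.15, adjusted p = 0.0067), touch (0.26, adjusted p = 0.011) and ethylene genes (0.15, adjusted p = 0.013) lay higher in 3xbhlh. Photosynthesis (-0.15, adjusted p = 0.0046), ER folding (-0.15, adjusted p = 0.013) and mitotic genes (-0.21, adjusted p = 0.015) lay lower. With an estimated correlation none of the 9 passed (adjusted p = 0.25 for auxin and adjusted p = 0.60 for the others). Heat shock medians on slides 1, 2 and 3 were 0.21, 0.30 and 1.51. With 1 array left out, the call was lost for ethylene genes without WT + SA replicates 1 or 3 or 3xbhlh + SA replicate 2 (adjusted p 0.058 to 0.18). ER folding genes lost it without WT + SA replicates 1 or 2 or the array labelled 3xbhlh + SA replicate 3 (adjusted p 0.19 to 0.64). Phenylpropanoid genes lost it without WT + SA replicate 1 or 3xbhlh + SA replicate 2 (adjusted p 0.055 to 0.11). Mitotic genes lost it without WT + SA replicate 1 or 3xbhlh + SA replicate 2 (adjusted p 0.14 to 0.36). Fe regulation genes lost it without WT + SA replicate 2 or the array labelled 3xbhlh + SA replicate 3 (adjusted p 0.065 to 0.11). Photosynthesis genes lost it without WT + SA replicate 3 or 3xbhlh + SA replicate 2 (adjusted p 0.14 to 0.80). Touch genes lost it without WT + SA replicate 3 or 3xbhlh + SA replicate 2 (adjusted p 0.069 to 0.39). Heat shock genes lost it without WT + SA replicate 3 (adjusted p = 0.52). A call arose for detoxification genes without WT + SA replicate 2 or 3xbhlh + SA replicate 1 (adjusted p 0.036 to 0.044). Root hair genes gained it without WT + SA replicate 2 or 3xbhlh + SA replicate 2 (adjusted p 0.017 to 0.048). Jasmonate genes gained it without WT replicate 3 (adjusted p = 0.0077). With the replicate block detoxification (0.05, adjusted p = 0.042) and jasmonate genes (0.11, adjusted p = 0.048) passed, and photosynthesis genes did not with quantile normalization (adjusted p = 0.097). Clock genes (-0.33 and 0.07) and SA synthesis genes (-0.02 and 0.01) had medians and means of opposite sign. Counts adjusted over the list alone, higher and lower, differed for root hair (1 and 0), root Fe acquisition (0 and 9), Zn and Cu (0 and 1), auxin (1 and 0), clock (2 and 2) and targeted (0 and 3).

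In all, 14 loci passed with SA, 7 higher and 7 lower in 3xbhlh, each in the same direction on all 3 slides. Of these 10 were among the 75 that passed without SA, in the same direction, where independent lists would share 0.023. With the replicate block 42 passed, and with the slide as a random block 30. The count moved to 59 without WT replicate 3, 8 without 3xbhlh replicate 2, 1 and 2 without WT + SA replicates 2 and 3, and 1 without either replicate 1 or replicate 2 of 3xbhlh + SA, and it was 45 without both WT replicate 3 and the array labelled 3xbhlh + SA replicate 3. M10 alone of the 14 passed whichever single array was left out. The call was lost for CYP82C4 without WT + SA replicates 2 or 3 or 3xbhlh + SA replicates 1 or 2 (adjusted p up to 0.087). AT3G07720 and ZIP8 lost it in 5 of the 12 cases (adjusted p up to 0.14). FAR6 lost it in 5 of the 12 cases (adjusted p up to 0.096). IDA lost it in 6 of the 12 cases (adjusted p up to 0.11). GRP17 lost it in 6 of the 12 cases (adjusted p up to 0.12). ATSBT5.2 lost it in 9 of the 12 cases (adjusted p up to 0.19). GH9C1 lost it in 10 of the 12 cases (adjusted p up to 0.15).

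Averaging the genotype difference over both treatments combined 6 arrays of each genotype. Of 24 root Fe acquisition genes 4 were lower in 3xbhlh (9 when adjusted over the list alone) and none higher. They were CYP82C4 (-2.33 ± 0.19, adjusted p = 7.7e-04), S8H, which acts before it in coumarin synthesis (-1.45 ± 0.26), ZIP8 (-0.82 ± 0.12) and the vacuolar metal transporter gene MTP3 (-0.70 ± 0.11). FIT (0.12 ± 0.07, adjusted p = 0.46), IRT1 (-0.20 ± 0.23, adjusted p = 0.74) and FRO2 (-0.35 ± 0.11, adjusted p = 0.15) did not pass. The IRT1 difference was made smaller by WT replicate 3, where IRT1 lay at 0.71 against 2.14 and 1.95 on the other mock WT arrays. The list median was -0.19 (camera adjusted p = 6.0e-05, and adjusted p = 0.43 with an estimated correlation); fry, which asks whether the genes of a list move and not whether they do so more than others, gave adjusted p = 0.011 for a net direction and 1.1e-05 for change in either direction. Of 11 clock genes 2 were higher, CCA1 (1.71 ± 0.23) and LHY (1.78 ± 0.24), and 2 lower, FKF1 (-0.71 ± 0.12) and LUX (-0.45 ± 0.08). The clock median (-0.39) and mean (0.22) had opposite signs, camera pointed down (adjusted p = 0.73), and the mixed fry test passed (adjusted p = 0.0019).

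PR5 was lower in 3xbhlh (-1.26 ± 0.22, adjusted p = 0.025), while NIMIN1 (-0.02 ± 0.19, adjusted p = 0.98) did not pass. The photosystem I gene PSAF (-0.62 ± 0.11) and the ferredoxin gene FD2 (-0.76 ± 0.15) were lower, and the efflux carrier gene DTX3 (0.82 ± 0.14), the auxin-induced SAUR15 (0.71 ± 0.15) and GH3.6 (0.32 ± 0.07) were higher. M10 (fitted difference 3.42 ± 0.20; WT not well above background), AT2G41250 (2.07 ± 0.16), AT5G54550 (1.65 ± 0.14) and AT3G28570 (1.72 ± 0.15) were higher, and AT4G04223 (-2.03 ± 0.16), AT3G21460 (-1.31 ± 0.12) and AT2G34655 (-1.28 ± 0.10) lower. By camera with the preset correlation, further lists passed: detoxification (0.15, adjusted p = 2.3e-04), ER folding (-0.17, adjusted p = 8.4e-04), phenylpropanoid (0.17, adjusted p = 0.0010), Fe regulation (0.19, adjusted p = 0.0023), auxin (0.13, adjusted p = 0.0028) and root hair genes (0.12, adjusted p = 0.030). With an estimated correlation none of these passed (adjusted p = 0.54 for ER folding, 0.48 for Fe regulation and 0.43 for the others). With 1 array left out, the call was lost for root hair genes without WT replicate 3, WT + SA replicate 3 or 3xbhlh + SA replicate 1 (adjusted p 0.091 to 0.18). Fe regulation genes lost it without WT replicate 2 (adjusted p = 0.066). A call was gained by SA signalling genes without WT replicate 1 or the array labelled 3xbhlh + SA replicate 3 (adjusted p 0.012 to 0.047). Mitotic genes gained it without WT replicate 3, 3xbhlh replicate 1, WT + SA replicate 3 or 3xbhlh + SA replicate 1 (adjusted p 0.0051 to 0.049). Photosynthesis genes gained it without WT replicate 3, 3xbhlh replicate 3, WT + SA replicate 1 or the array labelled 3xbhlh + SA replicate 3 (adjusted p 1.7e-04 to 0.034). Jasmonate genes gained it without WT replicate 2 (adjusted p = 0.022). Mitotic genes passed with the replicate block (-0.16, adjusted p = 0.048). Counts adjusted over the list alone, higher and lower, differed for SA synthesis (0 and 1), root hair (2 and 0), root Fe acquisition (0 and 9), Fe regulation (2 and 0), Fe storage (2 and 2), jasmonate (0 and 1), auxin (2 and 0), photosynthesis (1 and 4), clock (4 and 6) and reference (0 and 1).

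In all, 415 loci passed, 189 higher and 226 lower in 3xbhlh, 102 of them at least 2-fold. With the replicate block 1029 passed, and with the slide as a random block 1084. The count moved to 750 without WT replicate 3 and 172 without WT replicate 1, 156, 132 and 120 without 3xbhlh replicates 1, 2 and 3, 212 and 134 without WT + SA replicates 1 and 2, and 229, 104 and 182 without the arrays labelled 3xbhlh + SA replicates 1, 2 and 3. It was 474 without both arrays that stood apart. Of 26 named loci that passed, 17 did so whichever single array was left out, among them the targeted genes, CYP82C4, ZIP8, MTP3, CCA1, LHY and M10. The call was lost for FKF1 without 3xbhlh replicate 3 or WT + SA replicate 2 (adjusted p up to 0.056). DTX3 lost it in 6 of the 12 cases (adjusted p up to 0.069). PR5 lost it in 6 of the 12 cases (adjusted p up to 0.067). PSAF lost it in 7 of the 12 cases (adjusted p up to 0.072). LUX lost it in 8 of the 12 cases (adjusted p up to 0.075). S8H lost it in 8 of the 12 cases (adjusted p up to 0.077). FD2 lost it in 10 of the 12 cases (adjusted p up to 0.098). SAUR15 lost it in 10 of the 12 cases (adjusted p up to 0.14). GH3.6 lost it in 11 of the 12 cases (adjusted p up to 0.13).

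Whether the SA response itself differed between the genotypes was tested as an interaction. No locus passed in limma (smallest adjusted p = 0.9999), and 621 had an unadjusted p under 0.05. GH3.4 and AT5G17340, which were not well above background on any array with SA, ERF71 (-2.09 ± 0.39), ENODL10 (-0.69 ± 0.13) and AT1G05575 (1.02 ± 0.20) had the smallest p values and did not pass. Among SA genes the differences were 1.11 ± 0.34 for WRKY70 and 0.31 ± 0.38 for NIMIN1, and among Fe genes -1.05 ± 0.24 for ZIP8, -0.47 ± 0.10 for NAS1 and -0.69 ± 0.47 for IRT1, with no adjusted p below 0.99. Without WT replicate 3 they were 0.80 for WRKY70, -0.04 for NIMIN1 and -0.25 for IRT1. PR1 was not well above background on any mock array, so no difference is given for it. By camera with the preset correlation 8 of 22 lists passed: jasmonate (0.62, adjusted p = 2.5e-07), heat shock (0.98, adjusted p = 3.9e-07), SA signalling (0.28, adjusted p = 6.4e-04), ethylene (0.23, adjusted p = 6.4e-04), touch (0.26, adjusted p = 0.0031) and targeted genes (adjusted p = 0.033; no size is given, as BHLH100 and BHLH101 were dim on the 3xbhlh mock arrays) had a positive interaction, an SA change more positive in 3xbhlh, and detoxification (-0.15, adjusted p = 0.0039) and root Fe acquisition genes (-0.11, adjusted p = 0.012) a negative one. With an estimated correlation none passed (adjusted p = 0.31 for SA signalling and adjusted p = 0.51 for the others). Jasmonate medians with SA were -0.43 in WT and 0.25 in 3xbhlh, neither of which passed, and 0.14 in WT without WT replicate 3; the interaction medians were 0.11, 0.35 and 1.62 on slides 1, 2 and 3.

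With the replicate block 0 loci passed (997 at an unadjusted p under 0.05), as with the slide as a random block (914) and with array weights (899). The count was 3 without 3xbhlh replicate 1, 2 without WT + SA replicate 1, 1 without the 4 arrays of replicate 3, and 0 without both WT replicate 3 and the array labelled 3xbhlh + SA replicate 3. In fits lacking 1 array, the call was lost for targeted genes without WT replicates 1, 2 or 3, 3xbhlh replicates 1 or 2, WT + SA replicates 2 or 3 or the array labelled 3xbhlh + SA replicate 3 (adjusted p 0.050 to 0.32). Root Fe acquisition genes lost it without WT replicate 2, 3xbhlh replicate 3 or WT + SA replicate 2 (adjusted p 0.085 to 0.34). Touch genes lost it without WT replicate 2, 3xbhlh replicate 3 or WT + SA replicate 3 (adjusted p 0.097 to 0.12). Detoxification genes lost it without WT replicate 3 or 3xbhlh replicate 2 (adjusted p 0.084 to 0.11). It appeared for photosynthesis genes without WT replicate 1, 3xbhlh replicate 2, WT + SA replicate 1 or the array labelled 3xbhlh + SA replicate 3 (adjusted p 5.6e-06 to 0.048). Mitotic genes gained it without WT replicate 1, WT + SA replicate 3 or 3xbhlh + SA replicate 1 (adjusted p 0.018 to 0.046). Auxin genes gained it without WT replicate 3, 3xbhlh replicate 2, WT + SA replicate 1 or 3xbhlh + SA replicate 2 (adjusted p 0.0042 to 0.038). SA synthesis genes gained it without 3xbhlh + SA replicate 1 (adjusted p = 0.041, with a median of 0.05 in place of -0.0025). Fe regulation genes gained it without WT replicate 3 (adjusted p = 1.9e-04). Fe storage genes gained it without WT replicate 3 (adjusted p = 4.5e-04). ER folding genes gained it without the array labelled 3xbhlh + SA replicate 3 (adjusted p = 0.0025). Medians and means differed in sign for SA synthesis (-0.0025 and 0.20), camalexin (-0.02 and 0.04) and phenylpropanoid genes (-0.04 and 0.04).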

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

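The tests of explanations for the 2 arrays that stand apart were chosen only after the results were seen, and so was the fit without both; the list tests and the splits of the arrays were planned.

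The SA response of 8 gene lists differed between WT and 3xbhlh by the interaction test with the preset correlation, and none did with an estimated one (adjusted p = 0.31 and more). The interaction medians were 3.703 for targeted genes (a fitted value set by signals not well above background), -0.11 for root Fe acquisition, 0.28 for SA signalling, -0.15 for detoxification, 0.62 for jasmonate, 0.23 for ethylene, 0.98 for heat shock and 0.26 for touch genes. On slides 1, 2 and 3 they were, for the lists other than the targeted genes, 0.11, 0.35 and 1.62 for jasmonate, 0.22, 0.49 and 1.74 for heat shock, -0.01, 0.25 and 0.71 for SA signalling, -0.01, 0.12 and 0.82 for touch, 0.39, 0.01 and 0.36 for ethylene, -0.10, -0.21 and -0.14 for detoxification, and 0.02, -0.36 and 0.0024 for root Fe acquisition genes, whose negative value rests on slide 2. Slide 3 holds both arrays that stand apart. Without both, the targeted genes did not pass (adjusted p = 0.66), and the medians were 0.24 (adjusted p = 0.0071) for jasmonate, 0.97 (1.7e-07) for heat shock, 0.12 (0.0056) for SA signalling, 0.29 (0.0014) for touch, 0.23 (0.0010) for ethylene, -0.27 (3.4e-04) for root Fe acquisition and -0.08 (0.076) for detoxification genes. The adjusted p of the targeted genes ran from 6.3e-05 to 0.72 over 29 alternatives and that of jasmonate genes from 1.3e-10 to 0.65 over 29 alternatives. Fe regulation (-0.41, 7.4e-05) and Fe storage genes (0.62, 1.0e-05) passed without both arrays and did not with them. With a real interaction count of 0, all 100 drawn splits of the arrays reach it by construction (highest other 3), so the splits test nothing there.

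On the array labelled 3xbhlh + SA replicate 3 the targeted transcripts lay between the other arrays of their group and WT + SA. On the unlogged signal they lay at a median of 15.7% of the way from the former to the latter, on the log2 scale nearer to the latter. BHLH39, BHLH100 and BHLH101 lay below every WT + SA array, the lowest of which had 1.36, 1.48 and 0.34. This argues against an exchange with a WT + SA sample. WT replicate 2 was close for these genes, at -0.42, -0.15 and -0.55, but WRKY70 lay at -0.52 on it and at 5.65 on the array labelled 3xbhlh + SA replicate 3. Other loci were chosen on the 6 mock arrays alone, at an unadjusted p under 0.001 and at least 2-fold; the 30 lower in 3xbhlh lay at a median of 0.31 above the other 3xbhlh + SA arrays (24 above and 6 below), where the largest such distance among the other arrays with SA was 0.24, and the 29 higher in 3xbhlh lay at -0.17 (10 above and 19 below), where the largest was 0.12. Both directions are those of WT, but neither distance exceeds 2 times that of other arrays. That bound cannot decide: a small share of wild-type material would move loci that differ about 2-fold by little. The 0.24 is the distance of replicate 1 from replicate 2 alone. Among single loci, QQS (-3.07 against -5.18 and -6.34 on replicates 1 and 2) and AT4G04223 (0.15 against -0.79 and -0.78) lay toward WT. AT2G41250 (0.87 against 0.59 and 0.58) and FAR6 (-3.74 against -4.25 and -4.71) lay away from it. QQS also varied on the mock arrays of the mutant, at -7.17, -7.07 and -5.25 on 3xbhlh replicates 1, 2 and 3. Wild-type material in the sample and a change of the targeted genes alone both stay open. Regained activity of these genes, with other loci following, was not tested. Earlier forms of the test, which chose loci on 3xbhlh + SA arrays and favoured wild-type material, were dropped.

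WT replicate 3 lay over 2-fold from the other WT arrays at 8.69% of loci, 1058 higher and 910 lower, and by list medians of 2.02 for targeted, 0.98 for Fe regulation, -1.18 for Fe storage, 1.63 for jasmonate and 1.14 for aliphatic glucosinolate genes. Its low signal as the whole cause is argued against by the brightest loci, where 3.23% were over 2-fold away and at most 1.15% on any other array. A sample of another group under a wrong label is argued against by SA signalling genes, which differed by 0.016 where SA shifted them by 3.41, and by targeted genes above those of the other WT arrays. Stronger Fe deficiency in that sample stays open: Fe regulation and Fe storage genes lay beyond all matched random lists, and root Fe acquisition genes only at percentile 77.5, which decides neither way. The median of the latter was 0.08 above the other WT arrays, but their member IRT1 lay lower (0.71 against 2.14 and 1.95). FIT (2.09 against 2.11 and 2.22) and FRO2 (3.12 against 3.14 and 3.07) lay close to the other WT arrays. Differences of culture or harvest were not tested.

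Of 2640 kept probes without a locus and with a value on all arrays, outside the comparisons, 748 passed with SA in WT (311 higher and 437 lower) and 591 in 3xbhlh.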

How the results depend on the processing

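Named genes stayed on the same side of the threshold in 18440 cases, lost the call in 653, gained one in 214 and reversed in 0, and some values that passed in neither fit changed sign. Gene lists, with their direction by camera, did so in 3507, 203, 117 and 1. The reversed value is the Fe storage list for genotype without SA, with a median of -0.20 without both arrays that stand apart (adjusted p = 0.038) and a range of -0.20 to 0.37 with single arrays or replicate numbers left out. Except where stated, the cause of a change was not tested. Counts moved by over 1.5 times as follows. At an adjusted p under 0.01, 8 loci passed for genotype without SA, 1 with SA and 59 averaged, by construction fewer. With a 2-fold minimum, also by construction, 3574 passed for SA in WT, 3616 in 3xbhlh, 2946 in both and 102 averaged. Array weights gave 311 for genotype without SA, 23 with SA and 996 averaged; WT replicate 3 had a weight of 0.153. The replicate block gave 164, 42 and 1029, and the slide as a random block 181, 30 and 1084; for SA in WT, where the pairs did not all correlate, the block gave 12308. The block changed no other count beyond 1.5 times, and of list calls in these comparisons those of detoxification and jasmonate with SA and mitotic genes averaged. With the slide as a random block mitotic genes lost the call for SA in 3xbhlh (adjusted p = 0.062), and root hair and reference genes for genotype without SA (adjusted p = 0.060). No filter gave 31 without SA and 193 averaged, a filter on all 12 arrays 9 with SA and no value for BHLH100 and BHLH101, only the 6 arrays compared 13 without and 6 with SA, and a trended and robust spread 114 without SA. Without both arrays that stand apart 45 passed with SA; SA in WT, at 11568, moved by less than 1.5 times. With an estimated correlation 2 lists passed for SA in WT, 2 in 3xbhlh, 0 for genotype without SA, 0 with SA, 0 averaged and 0 for the interaction. By fry, 1 list passed for genotype without SA, 1 with SA, 2 averaged and 0 for the interaction.

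With each array or each replicate number left out in turn, SA in WT ranged from 6197 to 11488 loci, SA in 3xbhlh from 6312 to 12414 and loci shared by both from 4864 to 10237. Genotype without SA ranged from 0 to 93, with SA from 0 to 59, averaged from 0 to 750 and the interaction from 0 to 3. Lists ranged from 5 to 11 for genotype without SA, from 7 to 12 with SA and from 5 to 10 for the interaction. The averaged difference ranged from -6.14 to -4.89 for BHLH39, from -10.04 to -7.62 for BHLH100 and from -8.52 to -6.98 for BHLH101. These missed the threshold without replicate 1 or without replicate 2 in all groups, where 2 arrays a group remained. Signal over background limits the targeted genes in 3xbhlh, where the fitted values of BHLH100 and BHLH101 depend on signals not well above background.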

Other observations

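The test of linked DNA was chosen only after its result was seen; its control with the SA response and the splits of the arrays were planned.

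Of 8 common reference genes 3 passed with SA in WT, in both directions: UBQ10 rose by 0.48 ± 0.08, and ACT2 changed by -0.36 ± 0.10 and EF1A by -0.43 ± 0.14, with EF1A losing its call without WT + SA replicate 1 or 3 or WT replicate 3 (adjusted p up to 0.076). With quantile normalization ACT2 (-0.17, adjusted p = 0.13) and EF1A (-0.26, adjusted p = 0.11) did not pass, and with median centring EF1A did not (adjusted p = 0.052). Of the clock, PRR9, measured on 2 of 3 mock arrays, rose by 2.12 ± 0.43 and ELF4 fell (-1.41 ± 0.24). The nitrate transporter gene NRT2.1 fell (-1.57 ± 0.17), and the auxin genes SAUR9 (1.75 ± 0.22) and IAA19 (1.29 ± 0.18) rose. In the interaction, adjusted over the list alone, SARD1 (0.83 ± 0.21) and PBS3 (2.19 ± 0.57) of SA synthesis and ERF6 (0.92 ± 0.21) of the ethylene list were higher, and NAS1 and ZIP8 of root Fe acquisition lower. None passed over all loci, and with the mean of its probes SARD1 had an interaction of 0.01.

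Loci that passed between genotypes, averaged over treatments, gathered near the targeted genes, mainly near BHLH100. Among the 120 tested loci nearest to them, 20 on each side of each gene, 8 passed, against a mean of 2.18 in 10000 random placements (permutation p = 0.0019), so linked DNA around the mutated genes is a candidate explanation. Nearest BHLH100 were M10 (fitted 3.42, dim in WT), AT2G41250 (2.07), M17 (1.51), AT2G41380 (0.65) and AT2G41450 (-0.42), nearest BHLH39 ARR9 (0.40) and AT3G57160 (-0.50), and nearest BHLH101 AT5G03995 (0.45). Of as many loci with the smallest p for SA in WT, 4 lay there, which meets the bound set beforehand, at most 1 for every 2 of the genotype loci, but with a Poisson interval from 1.1 to 10.2 not by more than its spread, so neighbours that move together in any comparison stay open. Effects of the targeted proteins on these neighbours were not tested.

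For comparisons of a pair of groups the 10 splits of the 6 arrays, the real one included, are too few for a share under 0.05. All splits were fitted over the 22655 loci with a value on all arrays, so the real counts differ from those over all tested loci. The real split gave 11147 loci for SA in WT (highest other 0), 10816 in 3xbhlh (highest other 0), 77 for genotype without SA (highest other 0) and 14 with SA (highest other 1), each reached by 1 split. For the averaged difference 1 of 100 splits, the real one, gave as many as the real 407, and the highest other gave 3. This argues against a count that any division of the arrays would give. The share can be no lower than 1 in 100. The other splits mix the genotypes or, for the SA comparisons, the treatments, whose differences then widen the spread. The other splits also need not balance the slides as the real one does. With so many loci responding to SA, low counts in the mixed SA splits follow from the design and are no evidence.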
